A study of Danio rerio with 6 samples.

How the data were processed

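Histone H3 lysine 9 trimethylation (H3K9me3, spelled H3K9M3 in the labels) and lysine 9 acetylation (H3K9ac) were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in zebrafish heart tissue. Hearts were uncut or collected at 6 or 9 days post amputation (dpa) of the ventricle tip. There were 6 libraries, 1 for each mark and time. Per the labels' protocols, sonicated nuclei were used with commercial ChIP kits. Per the submitters' processing notes, the genome build was danRer10, and Bowtie2 2.2.5, MACS 1.4.2 and DiffBind 1.16.3 were used. The notes used here do not give the role or the settings of each tool, the control library, the read totals or the number of hearts pooled.

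For each library the authors deposited a separate list of peaks with RefSeq transcripts annotated to them. Per the file headers, each peak has a count of tags (reads) inside it, which was not normalized. The score in the deposited lists is 10 times the negative log10 of the peak's p, per the file headers; its lowest value was 50, a p of 1e-05. The fold enrichment is the authors' ratio of each peak to the background that the peak caller used, per the file headers. Scores and fold enrichments are the authors' values and were used to rank or filter peaks within a list. The score also served to recover each library's background, to match random lists and to rank named genes, as given below, and no score was compared between libraries as a change. Peak width was the remaining deposited value used. Peaks lay on 25 chromosomes. Coordinates are those of danRer10 as the lists give them.

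A gene carried a mark in a library when a peak overlapped the region from 2 kb before to 2 kb after one of its transcription start sites (TSS). The lists named 10299 transcripts of 10067 genes, 285 of which had no symbol. A gene that no list annotated was not counted, so shares of genes refer to these genes alone. Gene IDs were matched to the names and synonyms of the NCBI table of the GRCz12tu assembly, in which 9689 of 9783 were found. No coordinate was taken from that table. The 57 mir430 genes lie in 1 cluster and share the same peaks.

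Each peak's score and tag count together give the local read density against which it was scored, from the Poisson distribution. The most frequent density of a library was taken as its background in reads per kb, a measure of relative depth. Between 91.9% and 93.8% of the peaks of a library gave a density that fell within 0.002 of a whole step of 0.1 reads per kb, where chance gives 4.0%, or within 0.006 of the library's own background, which alone took 6.6% to 16.0%.

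Overlap between lists was counted with bedtools 2.31.1 at a minimum of 1 bp and set beside the mean of 100 circular shifts of the peaks along their chromosomes. Shares have Wilson 95% intervals, and all intervals cover counting error only. With 1 library per mark and time there was no replicate check, no p was computed between times, and every difference compares libraries, not conditions. A gene was counted as present at one time and absent at another when it had a promoter peak in one list and none in the other. An absent peak is one below the lowest score or outside the window, not a measured zero.

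The 19 gene lists were fixed before the data were examined: cardiomyocyte contractile and calcium handling, cardiac transcription factors, epicardium, endothelium and endocardium, fibroblast and extracellular matrix, regeneration signalling, AP-1 and immediate early, leukocyte and inflammation, erythrocyte and thrombocyte, cell cycle, H3K9 modifiers and readers, glycolysis and metabolic switch, neural and other-lineage transcription factors, markers of non-heart tissues, germline, hox genes, ribosomal proteins, mitochondrial respiratory chain, and genes with znf symbols. The comparisons of peak lists, their alternatives and the rule for named genes were chosen at the same point; the choices made after seeing the lists are named as such. A list's number of genes with a peak present after amputation and absent before was set beside 10000 random lists of equal size. These were matched on the decile of mean H3K9ac score over the H3K9ac libraries of all times, as a description of these libraries. For H3K9ac the match draws on the same peaks that are counted, so genes that changed tend to be matched with others that changed. A count that is not unusual among matched lists is therefore partly built in. Counts from lists without matching are given beside several.

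A further measure was chosen after the lists had been seen: the log2 ratio of a gene's H3K9ac promoter tags to those of the uncut library, relative to the median of the 8009 genes with an H3K9ac promoter peak at all times. That median was 0.11 at 6 dpa and 0.22 at 9 dpa before it was subtracted, while the log2 ratio of the backgrounds was -0.38 and 0.04. Scaled to the background instead, every value is higher by 0.49 at 6 dpa and by 0.18 at 9 dpa. Promoter tags sum over regions called separately in each library, so the change in tags per kb of called region is given beside the tag changes of lists and genes. Counting intervals came from 1000 Poisson draws, gene bootstraps, which show the spread between a list's genes, from 1000 resamplings of its genes, and a list's median was placed among 10000 lists matched on the decile of promoter tags, a placing that does not depend on the scaling. Beyond counting error, 1235 of the 8009 genes were lower and 1110 higher at 6 dpa, and 796 and 791 at 9 dpa. Counts of list members lower or higher are to be read beside these.

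Genes were named by a fixed rule. For each mark it took up to 10 genes with a promoter peak at 6 and 9 dpa and none in the uncut library, ranked by the lower of their 2 scores. It took up to 10 with a peak in the uncut library alone, and up to 5 each with a peak at 6 dpa alone and at 9 dpa alone, ranked by score. From each gene list it took up to 4 members present at both later times and not before, present before and at neither later time, or carrying the other mark. Genes with clone-type symbols were passed over in all but the lists. List members named for their tags, and those named for a count, were chosen after their values were seen.

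Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Overlap, gene counts and background were tested on simulated copies of each of the 6 libraries, and 100% of the planted values were recovered. For the tag measure, counts simulated from the uncut H3K9ac library in 8009 genes, with a planted list at a log2 change of -1, gave a median of -1.02. Alternatives were a score of at least 100, lists of equal length, windows of 1 and 5 kb, a reciprocal overlap of 50%, merging within 1 kb, thinning to equal background, lists not matched on acetylation, tags per kb, scaling to the background and leaving out the mir430 cluster. Of these, thinning, tags per kb, scaling to the background and leaving out the cluster were chosen after seeing the lists. An alternative filter on a false discovery rate was not run, because the lists used here have no such column.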

Results

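Zebrafish can rebuild the heart ventricle after its tip is removed. Here 2 marks on lysine 9 of histone H3 were mapped by ChIP-seq in heart tissue of fish aged 1 to 1.5 years: H3K9me3, typical of silent chromatin, and H3K9ac, typical of active promoters. Hearts were uncut or collected 6 or 9 days after amputation, so the comparisons ask where each mark lies before and during regrowth. Each mark and time had 1 library, and no difference between times has a replicate check. The H3K9me3 lists held 4488 peaks in uncut hearts, 6216 at 6 dpa and 4771 at 9 dpa, covering 5.16, 7.20 and 5.66 Mb. The H3K9ac lists held 16264, 17525 and 17223 peaks, covering 25.84, 28.34 and 28.47 Mb. Depth differed: the background was 4.10, 10.83 and 9.24 reads per kb for H3K9me3 in the same order, and 14.63, 11.25 and 15.01 for H3K9ac. Tags per kb in peaks were 11.61, 6.95 and 7.97 times the background for H3K9me3, and 5.03, 6.48 and 5.16 times for H3K9ac. Libraries thus also differed in enrichment, and its effect on which peaks were present or absent was not tested.

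A far larger share of H3K9ac peaks than of H3K9me3 peaks lay near promoters. In the uncut library 47.7% of H3K9ac peaks (Wilson 95% interval 46.9 to 48.4) lay within 2 kb of a TSS, against 3.0% of H3K9me3 peaks (2.5 to 3.5). At 6 dpa the H3K9me3 share was 6.0% (5.4 to 6.6), and at 9 dpa it was 2.6% (2.2 to 3.1). With peaks of a score of at least 100, the 6 and 9 dpa shares were 3.8% and 3.6%. H3K9ac shares at 6 and 9 dpa were 46.8% and 46.5%. The authors annotated no gene to 73.0% of uncut H3K9me3 peaks and to 42.5% of uncut H3K9ac peaks. The long arm of chromosome 4, known as heterochromatin in zebrafish and taken here from 28 Mb to the end, makes up 3.63% of the chromosomes' span. It held 10.6% of uncut H3K9me3 peaks (9.7 to 11.5), a density 3.14 times that of the rest of the genome, and this ratio was 3.61 at 6 dpa and 3.62 at 9 dpa. Of H3K9ac peaks it held 4.6%, 3.7% and 4.3%.

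H3K9ac peaks recurred between times more often than H3K9me3 peaks did. Of uncut H3K9ac peaks 85.8% (85.3 to 86.4) overlapped a 6 dpa peak and 87.9% (87.4 to 88.4) a 9 dpa peak, where shifted peaks gave a mean of 4.17% in both. Of 9 dpa H3K9ac peaks 84.7% (84.2 to 85.2) overlapped a 6 dpa peak. For uncut H3K9me3 peaks the shares were 57.1% at 6 dpa (55.6 to 58.5) and 53.0% at 9 dpa (51.6 to 54.5). Of 9 dpa H3K9me3 peaks 63.8% (62.4 to 65.2) overlapped a 6 dpa peak, and the mean after shifts was at most 1.17% in these comparisons. H3K9ac promoter peaks stood at 8009 genes in all 3 libraries, and H3K9me3 promoter peaks at 111. Many of these 111 were mir430 genes, which lie in 1 cluster and share the same peaks.

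At 6 dpa, H3K9ac peaks stood at promoters of DNA replication and mitosis genes that had none in uncut hearts, while promoters of heart muscle genes carried fewer H3K9ac tags. Across all genes, 599 had an H3K9ac promoter peak at 6 dpa and none before, and 189 the reverse. Of 35 cell cycle genes 22 had a peak in the uncut library and 31 at 6 dpa, 9 of them without one before. Among 10000 matched lists the mean was 4.93 such genes, and 189 lists had at least 9. They were birc5a, which encodes the mitotic protein survivin (55 tags), the cyclins ccna2 (85) and ccne1 (49), the mitotic kinase cdk1 (58), the replication licensing genes cdc6 (49), mcm2 (59), mcm3 (46) and mcm5 (53), and e2f7 (33). The birc5a TSS lies at 34334267 on chromosome 12 and that of cdk1 at 20903854 on chromosome 17. In the 21 cell cycle genes with a peak at all times, the median log2 change in tags was 0.19 (counting interval 0.04 to 0.30; gene bootstrap 0.01 to 0.27; 0.11 in tags per kb; 53 of 10000 lists as high). Examples were ccnb3 (0.99, and 0.05 per kb), cdkn1ba (0.56, and 0.27 per kb), mcm7 (0.44, and 0.20 per kb) and plk1 (0.41, and 0.21 per kb).

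Relative to the median gene, contractile and calcium handling genes had fewer H3K9ac tags at 6 dpa in all 9 members with a peak at every time, in 6 of them beyond counting error. Their median log2 change was -0.81 (counting interval -1.05 to -0.54; gene bootstrap -1.18 to -0.16), which none of 10000 lists matched on promoter tags reached. The median called width was 1768 bp before and 1521 bp at 6 dpa, and the change in tags per kb was -0.54; with tags scaled to the background the median was -0.32. The ventricular myosin heavy chain gene vmhcl, with its TSS at 24633990 on chromosome 2, had 146 tags before and 54 at 6 dpa (log2 change -1.55, standard error 0.23 from the counts; -0.88 per kb). Others were mybpc3, which encodes cardiac myosin-binding protein C (-1.18, and -0.42 per kb), tpm4a, a tropomyosin gene (-1.02, and -0.19 per kb), the myosin light chain genes cmlc1 (-0.85, and -0.56 per kb) and myl7 (-0.66, and -0.54 per kb), and atp2a2a, the calcium pump gene of the sarcoplasmic reticulum (-0.81, and -0.29 per kb). The thin filament genes tnnc1a (60 tags) and tnnt2a (67) had a peak in the uncut library and none at 6 dpa, while casq2 (45), cx43 (47) and smyd1b (27) had one at 6 dpa and none before; matched lists gave a mean of 3.99 such genes, and in lists of equal length there were 0.

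Cardiac transcription factor promoters also had fewer tags at 6 dpa relative to the median gene, with a median log2 change of -0.40 in 10 genes (counting interval -0.67 to -0.18; gene bootstrap -1.25 to -0.02; -0.25 per kb; 3 of 10000 lists as low), which was 0.09 when scaled to the background. Beyond counting error 5 were lower and 1 higher. They included tbx20 (-1.59, and -0.37 per kb), nkx2.5 (-1.32, and -0.29 per kb), gata4 (-0.79, and -0.64 per kb) and hand2 (-1.25, but 0.14 per kb). In the endothelium and endocardium list the median of 7 genes was -0.40 (-0.85 to -0.17; gene bootstrap -0.89 to -0.09; -0.29 per kb; 515 of 10000 lists as low), again 0.09 when scaled to the background. Beyond counting error 3 were lower and 1 higher. The lower ones were the vascular endothelial growth factor receptor genes kdr (-1.35, and -0.50 per kb) and kdrl (-0.88, and -0.76 per kb) and the junction gene esama (-0.89, and -0.29 per kb). Of all 16 genes in this list, 9 had a peak before and 11 at 6 dpa. Those of aplnrb, fli1b and tek were new and that of fli1a was absent. Of 10000 matched lists 7592 had as many new, and without matching 623 did. In the same library the erythrocyte and thrombocyte list had a median of 0.30 in 11 genes (0.09 to 0.42; gene bootstrap -0.05 to 0.47; 0.37 per kb; 50 of 10000 lists as high), 6 higher and 1 lower beyond counting error. Its members included cahz, the red cell carbonic anhydrase gene (0.44, and 0.37 per kb), and slc4a1a, the red cell anion exchanger gene (0.33, and 0.40 per kb).

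The AP-1 and immediate early list had a median log2 change in H3K9ac tags of 0.28 in 15 genes at 6 dpa (0.08 to 0.39; 50 of 10000 lists as high), and of -0.06 in tags per kb. Its genes varied, with a gene bootstrap of -0.03 to 0.36, 10 genes above 0 and 5 below, and 7 higher and 2 lower beyond counting error. Its AP-1 member junba had 127 tags over 2334 bp before and 239 over 3708 bp at 6 dpa (log2 change 0.80, 0.49 to 1.11; 0.17 per kb), and the phosphatase gene dusp1 had a change of 0.49 (0.37 per kb). In regeneration signalling 26 of 35 genes had a peak before and 30 at 6 dpa, 5 of them without one before. These were the chemokine receptor gene cxcr4b (61 tags), the Notch ligand genes dll4 (88) and jag1a (33), the fibroblast growth factor receptor gene fgfr4 (74) and the Wnt effector gene lef1 (32). Matched lists gave a mean of 5.23 and 6602 of 10000 had as many, and without matching 506 did. The list's median tag change was -0.16 in 23 genes (-0.26 to 0.01, and -0.12 per kb), with 5 lower and 3 higher beyond counting error. Of all 8009 genes, 1235 were lower and 1110 higher, so these counts do not set the list apart. The lower ones included socs3a, a cytokine signalling inhibitor gene (-0.74, and -0.49 per kb), and fgfr2 (-0.62, and -0.46 per kb), and the higher ones stat3, the cytokine signal transducer gene (0.63, and 0.10 per kb), and the growth factor gene igf2b (1.02, but -0.39 per kb).

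Some extracellular matrix and epicardial genes had a peak at 6 dpa and none before. Their numbers were not unusual among matched lists but were rare among lists without matching. In the fibroblast and extracellular matrix list, peaks stood at 8 of 17 genes before and 13 at 6 dpa. The 6 without one before were ctgfa (80 tags), the proteoglycan genes dcn (53) and vcanb (28), the fibronectin gene fn1b (38), sparc (86) and timp2b (40), and the collagen gene col5a2a (89 before) was absent. Matched lists gave a mean of 3.81, and 1150 of 10000 had at least 6; without matching, 2 of 10000 did. In the epicardium list 5 of 8 genes had a peak before and 7 at 6 dpa: wt1a (46 tags), wt1b (43) and aldh1a2 (45), the retinoic acid synthesis gene, had one at 6 dpa and not before, and the growth factor gene mdka (66 before) the reverse. Matched lists gave a mean of 2.16 for the 3 epicardial genes, and 3717 of 10000 had as many, while without matching 105 did. The median tag changes were -0.06 in 7 matrix genes (-0.03 per kb) and 0.12 in 4 epicardial genes (0.02 per kb).

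In the other fixed lists, respiratory chain genes had a median log2 tag change of -0.14 in 74 genes (-0.20 to -0.07; -0.08 per kb; 2 of 10000 lists as low) and ribosomal protein genes -0.11 in 75 (-0.16 to -0.03; -0.11 per kb; 3 as low), values of 0.36 and 0.38 when scaled to the background. Medians were 0.12 for genes with znf symbols (0.05 per kb), 0.06 for glycolysis and metabolic switch genes (0.03 per kb), 0.05 for H3K9 modifiers and readers (0.03 per kb), -0.16 for leukocyte and inflammation genes (-0.18 per kb) and -0.46 for 3 markers of non-heart tissues (-0.50 per kb), the last being 0.03 when scaled to the background. Scaled in this way, every list but the contractile genes had a median above 0 at 6 dpa, regeneration signalling and leukocyte genes at 0.33 and matrix genes at 0.43. Of the leukocyte list, coro1a (39 tags) and il10ra (22) had a peak at 6 dpa and none before (847 of 10000 matched lists had as many; 0 genes in lists of equal length). Of the modifiers, the histone deacetylase gene hdac9b (134 tags) and uhrf1 (80), whose product binds methylated H3K9, did so too (1132 of 10000 matched lists had as many). The hox genes hoxb2a (55 tags) and hoxb4a (65), of 3 hox genes in the lists, had a peak at 6 dpa alone (2614 of 10000 matched lists had as many; 1 gene in lists of equal length). Of 8 germline genes 2 had an H3K9ac peak in each library, and of 2 neural and other-lineage factors none did. An absent peak is one below the lowest score or outside the window. When a score of at least 100 was required where the peak was present, 133 genes had it at 6 dpa and not before, and 31 the reverse.

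At 9 dpa, erythroid promoters carried more H3K9ac tags than in uncut hearts, while contractile genes had a lower median with members on both sides of 0. Across all genes, 467 had an H3K9ac promoter peak at 9 dpa and none before, and 207 the reverse. The erythrocyte and thrombocyte list had a median log2 tag change of 0.30 in 11 genes (0.20 to 0.47; gene bootstrap 0.22 to 1.15; 0.16 per kb; 11 of 10000 lists as high), including the erythroid regulator gene klf1 (1.30, but 0.09 per kb), cahz (0.26, and 0.45 per kb) and slc4a1a (0.32, and 0.40 per kb). In 2 further members, the blood regulators gfi1b (197 tags) and gata1a (164), a peak was present at 9 dpa and absent before, while the beta globin gene ba1 (106 tags before) had none at 9 dpa; 2829 of 10000 matched lists had as many new members. The contractile list had a median of -0.43 in 9 genes (-0.63 to -0.17; gene bootstrap -0.70 to 0.17; -0.26 per kb; 4 of 10000 lists as low), 5 lower and 1 higher beyond counting error and 3 above 0, with atp2a2a at -0.87 (-0.28 per kb), tpm4a at -0.69 (-0.03 per kb), myl7 at -0.63 (-0.44 per kb) and vmhcl at -0.43 (-0.40 per kb). Its member mybpc3 was higher, at 0.50 (0.05 to 0.96; 0.00 per kb). Of its 17 genes 15 had a peak, and the myoglobin gene mb (261 tags before) was absent. New against the uncut library were casq2, cx43, smyd1b and tnni1b (44 tags). Of 10000 matched lists 3776 had as many, and without matching 60 did.

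Members of the cell cycle, endothelium, matrix and regeneration lists had an H3K9ac peak at 9 dpa and none before. Of 35 cell cycle genes 27 had a peak, 6 of them without one before: birc5a (84 tags), ccna2 (61), cdc6 (55), cdk1 (52), foxm1 (58), a mitotic transcription factor gene, and mcm5 (57). The mitotic kinase gene aurka (65 before) was absent. Matched lists gave a mean of 3.88, and 1584 of 10000 had at least 6; without matching, 55 did. Of 16 endothelial genes 12 had a peak against 9 before. The apelin receptor gene aplnra (57) and pecam1 (34) had one at 9 dpa alone, and aplnrb (222), fli1b (197) and the angiopoietin receptor gene tek (58) at 9 dpa as at 6 dpa, while fli1a (128 before) and egfl7 (87 before) were absent. Of 10000 matched lists, 943 had as many as these 5 new genes, and without matching 7 did. In the matrix list 12 of 17 genes had one, with fn1b (51), lox (57), the crosslinking enzyme gene, sparc (77) and timp2b (53) new (3133 of 10000 matched lists had as many; 65 without matching). Regeneration signalling had 30 of 35, with fgfr1a (41 before) and notch3 (69 before) absent. New were cxcr4b (63), dkk3 (50), dll4 (108), fgf17 (51), fgfr4 (74) and jag1a (45). Of 10000 matched lists 1903 had as many, and without matching 29 did. Median tag changes at 9 dpa were 0.14 for cardiac transcription factors (-0.01 to 0.27; 0.03 per kb), 0.10 for cell cycle genes (-0.03 per kb), -0.20 for endothelium (-0.17 per kb), -0.09 for AP-1 genes (-0.14 per kb), -0.10 for ribosomal proteins (-0.05 per kb; 0.08 when scaled to the background) and -0.06 for respiratory chain genes (0.00 per kb).

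Between 6 and 9 dpa, 271 genes had an H3K9ac promoter peak at 9 dpa and not at 6 dpa, and 421 the reverse. Members of most lists went both ways, and no matched lists were drawn for this comparison. Of the cell cycle genes aurka (60 tags at 6 dpa), ccne1, e2f7, mcm2 and mcm3 were present at 6 dpa and absent at 9 dpa, and foxm1 the reverse. Of the contractile genes tnnc1a (102 tags at 9 dpa), tnnt2a (64) and tnni1b were present at 9 dpa and absent at 6 dpa, and mb (64 at 6 dpa) the reverse. In the matrix list ctgfa, dcn and vcanb were absent at 9 dpa, and col5a2a (88) and lox were present there and not at 6 dpa. In the epicardium list wt1a and wt1b were absent at 9 dpa and mdka (81) was present. In regeneration signalling fgfr1a (41 at 6 dpa), lef1 and notch3 (62 at 6 dpa) were absent at 9 dpa, and dkk3, fgf17 and vegfc (56), a vascular growth factor gene, were present there and not at 6 dpa. The glycolytic genes pfkmb (44 tags at 6 dpa), pgam2 (25) and eno1b (55) were absent at 9 dpa. Among transcription factor genes, mef2ca (50), meis1b (650), gata1a and egr1 (59) were present at 9 dpa and not at 6 dpa, and tbx2a (49 at 6 dpa) and egr3 (45 at 6 dpa) the reverse. Of the cardiac factors 12, 11 and 12 of 15 had a peak in uncut, 6 dpa and 9 dpa hearts, and in lists of equal length 0 were new at 9 dpa. With scores of at least 100 where present, the counts were 47 and 58, and thinned to equal background 167 and 615.

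**Figure D1:**
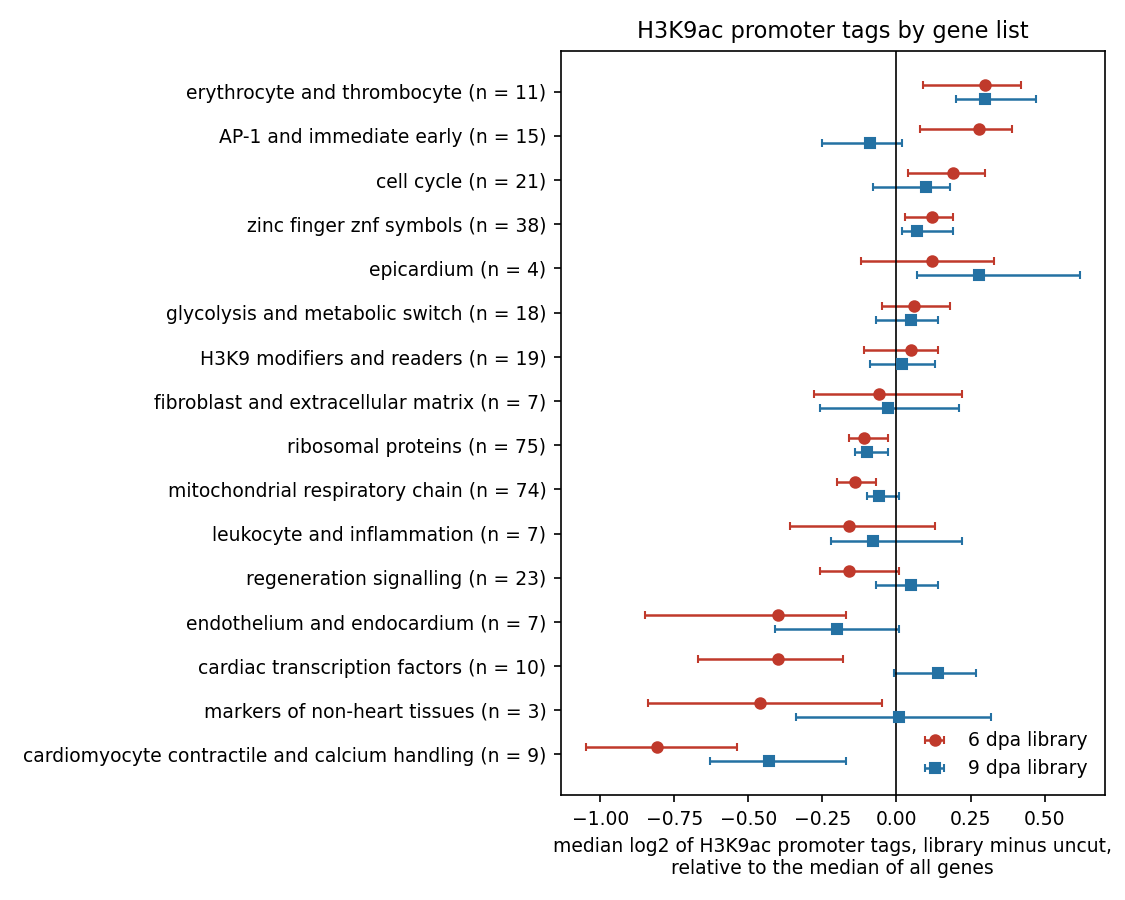
Median log2 change in H3K9ac promoter tags against the uncut library, relative to the median gene, for each gene list at 6 and 9 dpa; bars are counting intervals from 1 library per time. Contractile genes lie lowest at 6 dpa (-0.81), and scaled to the background they alone would lie below 0 at 6 dpa (-0.32), with contractile (-0.25) and endothelial genes (-0.02) at 9 dpa; per kb the AP-1 point at 6 dpa would be -0.06 and the epicardium point at 9 dpa -0.02.

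An H3K9ac promoter peak at 6 and 9 dpa and none in uncut hearts was found at 319 genes. The highest by the lower of their scores were kctd7 (248 tags at 6 dpa and 205 at 9 dpa), stpg2 (108 and 114), tbc1d19 (55 and 59), igfbp1a (254 and 266), an insulin-like growth factor binding protein gene, and atp1b1a (543 and 565), a sodium pump subunit gene. Next came arpc1b (179 and 142), an actin nucleation gene, ddit4 (163 and 137) and gadd45ab (87 and 130), both stress response genes, aplnrb (184 at 6 dpa) and fgfr4. The igfbp1a peak at 6 dpa spanned 6821976 to 6824696 on chromosome 20, and that of aplnrb 8669699 to 8673032 on chromosome 10. The 66 genes with a peak in uncut hearts alone were led by ing5b (211 tags), isl1 (86), a heart progenitor factor gene, fli1a (128), sall1a (215), mtfr1 (143), mapre3a (44), pold1 (76), fbxl22 (94), phyhd1 (42) and apobec2b (72). The isl1 peak spanned 40134364 to 40136121 on chromosome 5. Of 280 genes with a peak at 6 dpa alone the highest ranked were mibp (501 tags), rwdd3 (54), kitlga (86), mapk12a (58) and plcd1b (75). Of 148 at 9 dpa alone they were asb16 (178), napg and rab12, which share a peak (100), scn4ba (108), a sodium channel subunit gene, and mir1-2 (183), a muscle microRNA gene. Some of these peaks only reached the edge of the promoter window: that of kctd7 at 9 dpa began at 32948757, with the TSS at 32946757. Peaks of stpg2, ing5b, rwdd3, asb16, napg and rab12 also lay near that edge. At such genes a small shift of a called boundary can make a peak present or absent.

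H3K9me3 promoter peaks at 6 dpa stood at more genes than in uncut hearts. Promoter peaks stood at 198 genes before and 463 at 6 dpa: 326 had one at 6 dpa and not before, 61 the reverse. Of the 198 and the 463, 56 and 57 were genes of the mir430 cluster. Of 76 respiratory chain genes none had one before and 6 did at 6 dpa: atp5ib, cox5b2, cox6a2, ndufa11, ndufb8 and uqcrc1. Matched lists gave a mean of 3.19, and 1027 of 10000 had at least 6 (344 without matching); in lists of equal length the count was 2. Other list members with a peak at 6 dpa alone included socs3b, jund, pcna, the H3K9 methyltransferase gene setdb1a, eno1a, pdk4, znf143a and znf592. Such counts were not unusual: of 10000 matched lists, 5379 had as many for regeneration signalling, 4571 for AP-1 and 5432 for cell cycle genes. For modifiers, glycolysis and znf genes 6212, 1968 and 5455 did. Among the 298 genes with a peak at 6 dpa alone the highest ranked were tlk1a (52 tags), nipal4 (38), nubp2 (58), tbl3 (42) and stt3b (49). With a score of at least 100 where present, 20 genes had a peak at 6 dpa and not before and 2 the reverse, and in lists of equal length the first count was 173. The 6 dpa library had 2.64 times the background of the uncut library, and thinned to equal background the counts turned to 14 and 100, with 1412 peaks left at 6 dpa against 4488.

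At 9 dpa the number of genes with an H3K9me3 promoter peak was 184, of which 56 were mir430 genes. There were 65 not present before and 79 lost from the list, although the background was 2.25 times that of the uncut library. The 28 genes with a peak at both later times and none before were led by mccc2 (93 tags at 6 dpa and 69 at 9 dpa), an enzyme gene of leucine breakdown, pmt (37 and 39), fam210b (64 and 37), and acads (51 and 46), an enzyme gene of short-chain fatty acid oxidation. The others named were the proteasome gene psmd3 (75 and 68), eps8 (80 and 50), nrip2 (124 and 77), eif4e2 (44 and 38), a cap-binding protein gene, rab32a (35 and 26) and klf7a (31 and 22). The mccc2 peak at 6 dpa spanned 43219617 to 43221279 on chromosome 5. The 53 genes with a peak in uncut hearts alone were led by ccnt2a (15 tags), cldn15la (17), stxbp2 (17), btr09 (16), tmem144a (18), rnf170 (34), cnpy2 (19), tfec (24), anxa3b (20) and tm4sf18 (20), and held ehmt2, an H3K9 methyltransferase gene. The peaks of rnf170 and tm4sf18 lay near the edge of the promoter window. With a score of at least 100 where present, 7 genes had a peak at 9 dpa and not before and 4 the reverse; thinned to equal background, the counts were 8 and 97.

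Against 6 dpa, the 9 dpa library had 45 genes with a new H3K9me3 promoter peak, and 324 with a peak at 6 dpa had none. Of 37 genes with a peak at 9 dpa alone, the highest ranked were the protease gene capn3a (1287 tags, with a local background of 202 reads per kb), the ribosomal stalk gene rplp0 (126), caskb (23), ndufa5 (36), a subunit gene of respiratory complex I, and cpeb3 (48). The AP-1 member fosl2 also had one at 9 dpa alone. The peaks of capn3a and rplp0 lay at the edge of the promoter window. In all 3 libraries a peak stood at pax3a, a neural crest and muscle factor gene (56, 63 and 55 tags in uncut, 6 dpa and 9 dpa hearts), and at rps6 (123, 256 and 269). With scores of at least 100 where present, the counts were 3 and 26, and in lists of equal length 46 and 172. Thinned to the uncut background they were 16 and 19, and at 8 background reads per kb 44 and 144.

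Most genes with an H3K9me3 promoter peak also had one of H3K9ac in the library of the same time. They numbered 156 of 198 in uncut hearts (78.8%, 72.6 to 83.9), 431 of 463 at 6 dpa (93.1%, 90.4 to 95.1) and 152 of 184 at 9 dpa (82.6%, 76.5 to 87.4), where 82.8%, 86.9% and 85.4% of all genes had H3K9ac. Without the mir430 genes the shares were 71.1%, 92.4% and 75.8%. The 10 named genes with H3K9me3 at both later times, mccc2 and acads among them, all had an H3K9ac peak in uncut hearts and at 6 dpa, and all but nrip2 at 9 dpa. Of the 10 named with H3K9me3 in uncut hearts alone, cldn15la and tfec had no H3K9ac peak in any library and tm4sf18 had one at 6 dpa only. The gene pax3a had none, while rps6 carried both marks. Over the whole genome 32.6% of uncut H3K9me3 peaks (31.2 to 33.9), 40.2% at 6 dpa (39.0 to 41.4) and 43.8% at 9 dpa (42.4 to 45.2) overlapped an H3K9ac peak of the same time, against 3.33%, 3.63% and 3.60% after shifts. By decile of H3K9ac promoter tags at 6 dpa, 2.17% of genes in the lowest decile and 9.67% in the highest (79 of 817) had an H3K9me3 promoter peak at 6 dpa, while in the 9 dpa H3K9me3 library the shares were 1.82% and 1.71%.

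**Figure D2:**
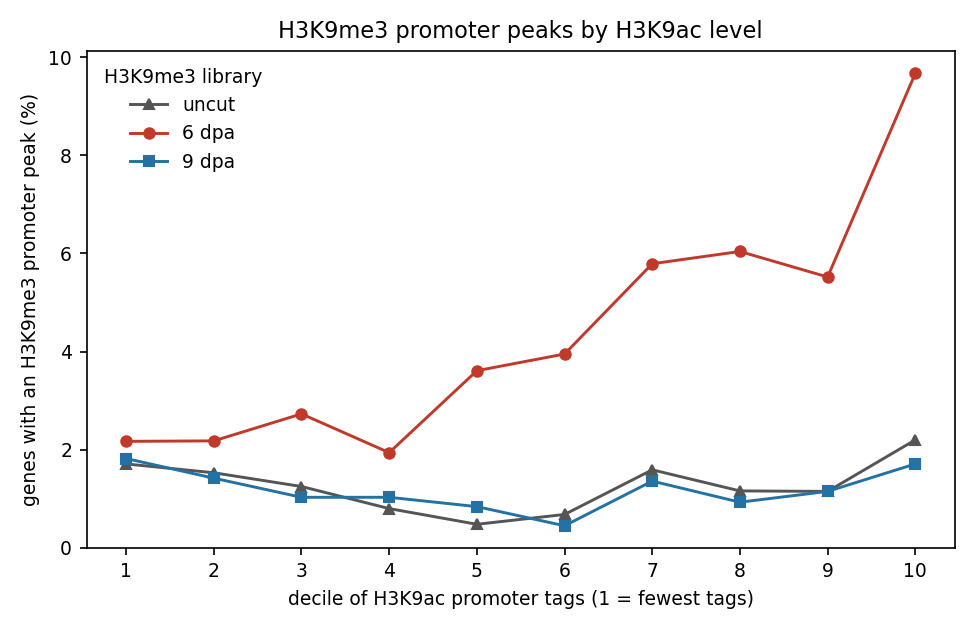
Percent of genes with an H3K9me3 promoter peak by decile of H3K9ac promoter tags at 6 dpa, for the uncut, 6 dpa and 9 dpa H3K9me3 libraries, 1 library each, mir430 genes left out. In the highest decile the 6 dpa library has 79 of 817 genes, the uncut library 18 and the 9 dpa library 14.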

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

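The tests of cell shares and of region width, and the depth test between 6 and 9 dpa, were chosen after related results were seen, as were promoter tags as a measure. Genes with an H3K9me3 promoter peak numbered 265 more at 6 dpa than in uncut hearts and 14 fewer at 9 dpa (a net of -14), so the 2 times went opposite ways; the difference was not tested, and thinned to equal background both times had fewer genes than uncut hearts (14 gained and 100 lost at 6 dpa, 8 and 97 at 9 dpa). The cardiac transcription factor list had a median H3K9ac tag change of -0.40 at 6 dpa and 0.14 at 9 dpa, and the AP-1 and immediate early list 0.28 at 6 dpa and -0.09 at 9 dpa. Neither difference between times was tested, and the 6 dpa values were 0.09 for cardiac factors when scaled to the background and -0.06 for AP-1 genes per kb.

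H3K9me3 peaks at 6 dpa alone stood at promoters such as those of tlk1a, ndufb8 and cox5b2. Depth against the uncut library cannot be told apart from a change in the mark: thinned to its background, genes at 6 dpa alone numbered 0.13 times the larger of the other counts (12 against 90), which met the bound set for depth, but thinning can only shorten the deeper lists and left 1412 peaks at 6 dpa against 4488, so the rule was changed after that value was seen. Between the later times the values at 8 reads per kb argue against depth, since with 3958 against 3902 peaks genes at 6 dpa and not 9 dpa were 3.27 times the reverse (144 against 44), although thinned to the uncut background, where 112 and 109 genes were left, the counts were 19 and 16 and no difference was detectable. At the 278 of these 298 genes with an H3K9ac peak at all times, H3K9ac tags had a median change of 0.11. Matched lists had a median of 0.05, and 0.11 stood at percentile 100. For these 278 genes as a set, a replacement of H3K9ac by H3K9me3 is argued against. Genes that lost their H3K9ac peak were left out of this test, and 282 of the 298 had one at 6 dpa. Replacement in a part of the cells cannot be seen in whole tissue. A candidate explanation that remains is reads from open, strongly acetylated promoters. The genes at 6 dpa alone had a median percentile of 72.9 in 6 dpa H3K9ac tags. Of their H3K9me3 peaks 87.3% overlapped an H3K9ac peak. Of all 6 dpa H3K9me3 peaks 40.2% did, but only 6.0% of those lay within 2 kb of a TSS. By gene, 86.9% of all genes had an H3K9ac promoter peak at 6 dpa, which is not a share of overlapping peaks. A like share for promoter peaks in general was not computed, so the 87.3% decides little. A real gain of the mark at such promoters stays untested.

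Contractile genes such as vmhcl, mybpc3 and atp2a2a had lower H3K9ac tags at 6 dpa. A loss at all strongly acetylated promoters is argued against, since 0 of 10000 lists matched on promoter tags had a median as low. Relative to the median gene, narrower calling as the whole cause is argued against too, with a median of -0.54 per kb. The median gene's own log2 change in tags per kb was 0.07, while that of the background was -0.38. Scaled to the background, the list's change per kb would be much smaller, so narrower calling cannot be decided in that scaling. A smaller share of cardiomyocytes as the only change would raise the markers of every other cell type alike. The lowest of these lists, endothelium, was at -0.40 in 7 genes (gene bootstrap -0.89 to -0.09). It lay below the highest of them, the erythrocyte list, by a difference of -0.70 (gene bootstrap -1.35 to -0.07). Scaling cannot move that gap, which was added after the medians were seen. The pair was taken as the lowest and the highest list, and the interval does not allow for that choice. The gap therefore cannot decide against this change alone. Nor can it decide against a smaller cardiomyocyte share joined by unequal changes in other cells. Scaled to the background, the endothelium median was 0.09 and contractile genes alone lay below 0. A smaller share of cardiomyocytes, and a larger share of blood cells, therefore stay open. Lower acetylation within heart muscle cells after amputation may contribute, as a hypothesis that 1 library per time cannot test.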

How the results depend on the processing

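Thinning, tags per kb, scaling to the background, leaving out mir430 genes and all settings of promoter tags were chosen after seeing the data. Over 375 alternatives to 156 values, 233 agreed within counting error or 1.5 times, 134 moved and 8 reversed; of these, 29 that moved and 7 that reversed concern results of lesser weight. The cause of the moves below was not tested, except that a stricter score, a longer or shorter window, thinning and equal lengths change the number of peaks or genes by construction. No paired analysis was possible because each mark and time had 1 library. No filter on a false discovery rate was run, as the lists used here have no such column; all peaks lay on chromosomes 1 to 25, so that setting moved nothing, and merging within 1 kb moved no result. Depth may limit comparisons of the H3K9me3 counts with the uncut library, which was the shallowest.

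With a score of at least 100 in both libraries, H3K9me3 promoter genes present later and absent earlier, then the reverse, numbered 42 and 9 (6 dpa against uncut), 19 and 8 (9 dpa against uncut) and 13 and 35 (9 against 6 dpa). With that score where present, they were 20 and 2, 7 and 4, and 3 and 26, and for H3K9ac 133 and 31, 89 and 24, and 47 and 58. Thinned, the H3K9me3 counts were 14 and 100 at 6 dpa, 8 gained at 9 dpa, and 16 and 19 between 6 and 9 dpa, and H3K9ac had 167 gained at 9 against 6 dpa. In lists of equal length 173 were gained at 6 dpa and 172 lost at 9 against 6 dpa, and respiratory chain genes gained 2. A window of 1 kb gave 29 gained at 9 against 6 dpa; 5 kb gave 143 lost at 6 dpa, 151 gained and 165 lost at 9 dpa, and 99 gained at 9 against 6 dpa.

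Overlap of uncut peaks with 6 dpa, of uncut with 9 dpa and of 9 dpa with 6 dpa, in that order, was 53.9%, 49.9% and 60.9% for H3K9me3 and 84.1%, 86.4% and 83.1% for H3K9ac at 50% reciprocal overlap. It was 68.9%, 65.0% and 72.7%, and 91.3%, 92.3% and 90.6%, at a score of at least 100. In lists of equal length it was 51.1% (uncut with 6 dpa) and 58.3% (9 with 6 dpa) for H3K9me3, and 83.8%, 86.0% and 85.6% for H3K9ac. Thinned, it was 26.6% and 27.5% for uncut H3K9me3, and 90.5%, 88.9% and 90.8% for H3K9ac. H3K9me3 peaks on H3K9ac peaks in uncut, 6 dpa and 9 dpa hearts made 41.9%, 43.4% and 50.6% at a score of at least 100 and 27.7%, 78.5% and 67.3% when thinned. Genes with both marks were 82, 111 and 85 at that score, 106 at 6 dpa and 97 at 9 dpa when thinned, 308 (uncut) and 306 (9 dpa) at 5 kb, and 101 (uncut) and 97 (9 dpa) without mir430.

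At a score of at least 100 the H3K9me3 lists held 1179, 1722 and 1388 peaks and the uncut H3K9ac list 10812. The chromosome 4 share was then 13.0% for uncut H3K9me3 and 3.4%, 2.5% and 3.0% for H3K9ac. The share near a TSS was 3.8% and 3.6% for H3K9me3 at 6 and 9 dpa, and 58.7%, 58.0% and 57.8% for H3K9ac. Within 1 kb it was 1.9%, 4.8% and 1.6%, and 46.6%, 45.6% and 45.4%; within 5 kb 6.6%, 9.3% and 6.1%, and 50%, 49.2% and 48.8%.

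Of 10000 lists not matched on acetylation, as many genes were gained in 2 (matrix, 6 dpa), 65 (matrix, 9 dpa), 0 (cell cycle, 6 dpa), 55 (cell cycle, 9 dpa) and 344 (respiratory chain H3K9me3, 6 dpa). In tags per kb the contractile median at 6 dpa was -0.54, and the AP-1 median at 6 dpa and the epicardium median at 9 dpa reversed to -0.06 and -0.02. At a score of at least 100 the cardiac factor median at 9 dpa was -0.24. Scaled to the background, medians at 6 dpa reversed to 0.09 for cardiac factors, 0.09 for endothelium, 0.03 for non-heart markers, 0.38 for ribosomal and 0.36 for respiratory genes, and at 9 dpa to 0.08 for ribosomal genes. In that scaling the contractile median at 6 dpa was -0.32, the cardiac factor median at 9 dpa 0.32, and the cell cycle medians 0.68 and 0.28 at 6 and 9 dpa.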

Other observations

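The test of extra sequence copies had its bound set beforehand, but its values at unsaturated sites and the check of the depth scaling, and the ranking of genes by tags in regions of similar width, were chosen after the values were seen. Of 5554 genes with an H3K9ac promoter peak at all times and at least 100 tags in 1 library or more, 313 were higher and 271 lower than the median gene beyond counting error at both 6 and 9 dpa, 115 and 103 of them with similar called widths. Both changes use the same uncut library, so a low or high uncut count moves both times the same way. Agreement between the times is therefore not independent, and no number by chance was computed. Among the higher were egln1b, an oxygen-sensing prolyl hydroxylase gene (log2 change 0.66 at 6 dpa and 0.53 at 9 dpa, with 0.63 and 0.44 per kb), the mitophagy gene bnip3lb (0.44 and 0.64, with 0.21 and 0.42 per kb), the autophagy gene wipi1 (0.64 and 0.52, with 0.52 and 0.48 per kb), hmox2a, a heme oxygenase gene (0.65 and 0.55, with 0.37 and 0.55 per kb), the interferon-stimulated gene isg15 (0.58 and 0.52, with 0.55 and 0.47 per kb), the ubiquitin ligase gene march8 (0.92 and 0.86, with 0.89 and 0.69 per kb) and the corepressor gene bcor (0.44 and 0.53, with 0.23 and 0.33 per kb). Among the lower were dkc1, needed for ribosomal RNA modification (-0.73 and -0.86, with -0.87 and -0.82 per kb), the deoxycytidine kinase gene dck (-0.88 and -0.70, with -0.66 and -0.43 per kb), the NF-kB gene rel (-0.91 and -0.64, with -0.84 and -0.50 per kb), the chaperone gene hspa8 (-0.69 and -0.40, with -0.44 and -0.15 per kb), and cand2 with sec13, which share a peak (-1.07 and -0.83, with -0.85 and -0.54 per kb). These genes were chosen after their values were seen, and scaled to the background each tag change is higher by 0.49 at 6 dpa and 0.18 at 9 dpa, which leaves the directions of these tag changes as given; the values per kb were not scaled in this way, and that of hspa8 would then be close to 0.

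Genes of the H3K9 machinery itself had H3K9ac peaks in most libraries. The methyltransferase genes suv39h1b and ehmt1b had more tags at 6 dpa (0.54, 0.79 per kb, and 0.49, 0.38 per kb), while the methyltransferase gene ehmt1a and the deacetylase gene hdac3 had fewer (-0.55, -0.06 per kb, and -0.50, -0.54 per kb), around a list median of 0.05 (0.03 per kb). The NF-kB gene nfkb2 (1.08, and 0.12 per kb) and the myeloid factor gene cebpa (0.52, and 0.57 per kb) were higher, while cd74a, an antigen presentation gene, was lower (-1.34, and -0.73 per kb), all relative to the median gene. H3K9me3 promoter peaks in all libraries also stood at ghitm (163, 278 and 203 tags in uncut, 6 dpa and 9 dpa hearts), elp5 (375, 824 and 762) and zswim6 (128, 181 and 125), which carried H3K9ac as well.

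Many places carried both marks at every time: of 2018 merged sites in all 3 H3K9me3 lists, 967 (47.9%, 45.7 to 50.1) were also in all 3 H3K9ac lists, 36 of them near a TSS, and the 50 highest-scoring uncut H3K9me3 peaks all overlapped an uncut H3K9ac peak. Sequence present in more copies than the assembly holds is a candidate explanation, under which depth-scaled tags would be alike in both marks, with a median absolute log2 ratio of at most 0.5. It was 1.07 (1.02 to 1.12), beyond the bound of 1 set against this explanation, and 1.00 (0.95 to 1.05) at 767 sites of at most 0.1 tags per bp. That bound did not allow for the depth scaling: a peak needed at least 11 tags in the uncut H3K9me3 list and 21 in the uncut H3K9ac list, a log2 ratio of 0.90 after scaling, and at these sites H3K9me3 itself differed by -0.45 and -0.47 between the uncut and the 6 and 9 dpa libraries. At the 20 highest-scoring sites, raw tags in the uncut libraries were nearly alike (median log2 ratio of H3K9me3 to H3K9ac -0.12). The backgrounds differed by -1.83, and the depth-scaled ratio was 1.71. Tags at these top sites were thus alike despite the difference in depth, and cannot be read as amounts of either mark. From these values extra copies and a real presence of both marks cannot be told apart. No control library was used here, and whether the peak calling used one is not given. No biological explanation was tested.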
